A study of Rattus norvegicus with 9 samples.

How the data were processed

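Tibia samples of male Sprague Dawley rats (Rattus norvegicus) were sequenced as total RNA, which per the labels was extracted on columns with a DNase step. The labels place 9 libraries in 3 groups of 3: Model (replicates 1, 2 and 5), GelMA (replicates 2, 3 and 4) and PMLGH (replicates 2, 3 and 4). GelMA is the usual short name of gelatin methacryloyl, a gelatin that is cross-linked into a hydrogel. The labels do not expand PMLGH, describe what was done to the Model group, or give the time of sampling, and these are not guessed here. The labels also do not state that each replicate is a separate animal, so the p-values below may measure technical spread in part.

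The deposited count table holds raw counts per gene symbol, which the authors made without further scaling. The deposited FPKM table holds FPKM, fragments scaled to gene length and to the total of the library, which the authors computed per library. The submitters name DESeq2 and R 3.2.0 and give no DESeq2 version or role for either. The aligner, the counting tool, the genome build, the annotation and the strand of counting are not given in the sources used here, so antisense reads cannot be told apart and no coordinates are printed. Both tables hold 23768 genes, of which 970 have 0 counts in every library. Each FPKM equalled the count divided by the library total and by 1 length per gene, within a relative tolerance of 0.0001, for all 22798 other genes, so the FPKM add no independent measurement. All 9 columns of each table matched 1 label each.

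Total counts per library ran from 34571478 to 37166383. Of the gene symbols, 20533 matched a reference table of rat genes, 500 more matched through older names, and 2735 did not match. That table was used for names only. Counts of near-identical gene copies depend on an unstated rule for reads with several matches. The values of the globin genes, RT1-A3, Defa5, Sirpd, Fcgr3a, Prss34, Prss29, Bin2a, Zfp955a, Olr1433, C4a, C4b and the myosin heavy chain genes are therefore uncertain. Replicates of a group were compared gene by gene with a chi-square statistic over genes with a mean count of at least 50, and no pair of libraries was a copy of another.

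Gene tests used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group as the design, which left 16816 genes, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 9 libraries, with 6 residual degrees of freedom. The 3 comparisons were PMLGH against Model, GelMA against Model and PMLGH against GelMA. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and adjusted p under 0.05 counted as passing. The common biological coefficient of variation was 10.1%. Levels are CPM, counts scaled to the TMM-adjusted library total, given as mean ± SD over n = 3 libraries per group. The ± after a log2 fold change is an approximate SE, the size of that change divided by the square root of its F statistic. It can be too small where a group has few counts, as for Cxcl2 in Model. Counts of 0 were bounded by a floor of 3 counts per library, and ratios with 1 to 3 counts carry a 95% counting interval. Both cover counting error only.

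A total of 33 gene lists with 856 symbols was written from general knowledge, and 838 symbols matched. They cover lysyl oxidase and collagen cross-linking, collagens, osteoblasts, osteocytes, osteoclasts, chondrocytes, matrix proteases, TGF-beta and BMP, Wnt, fibroblasts and periosteum, endothelium, macrophages, alternatively activated macrophages, pro-inflammatory mediators, neutrophils, B cells, T and NK cells, erythroid cells, megakaryocytes, mast cells, skeletal muscle, adipocytes, peripheral nerve, antioxidants, AGE-RAGE, glycolysis, oxidative phosphorylation, cell cycle, interferon response, immediate early genes, mitochondrially encoded transcripts, hypoxia and the unfolded protein response. Lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, again with the correlation estimated per list, and with fry. Camera compares a list with all other genes, and fry asks whether the members move one way on balance. A gene may belong to more than 1 list. Members were also adjusted over the list alone. The lists, the model, the comparisons, the alternatives and the rule that picks the named genes were chosen before the data were examined. That rule names, per comparison, the 8 largest rises and 8 largest falls among passing genes with a mean of at least 1 CPM, a gene name that is not a placeholder and no overlap between libraries. It adds up to 4 members of smallest p per described list, and always Lox, Col1a1, Runx2, Bglap, Acp5 and Ctsk. The text below takes its examples from those members in order of p, passing over some whose call was lost when a library was left out. Values of single libraries were compared with exact two-sided permutation tests, whose smallest possible p for 3 against 3 is 0.1.

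The model was tested on simulated data of 16816 genes, with changes of 1.5-fold and 2-fold planted in 67 genes each and of 4-fold in 66. It recovered 67.2%, 59.7% and 67.2% of 1.5-fold changes in PMLGH against Model, GelMA against Model and PMLGH against GelMA, in that order. At 2-fold it recovered 79.1%, 79.1% and 61.2%, and at 4-fold 87.9%, 93.9% and 92.4%. False calls were 6 of 171, 10 of 179 and 10 of 166. A list raised 1.3-fold was called in each comparison, and 0 of 10 unchanged lists was called. Simulated genes were drawn independently of each other, so this check says nothing about false list calls where members vary together.

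Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, other filters on low counts, only the 6 libraries compared, limma on log2 FPKM with pseudocounts of 1 and 0.1, a robust spread, stricter thresholds, the replicate number as a block, fry and the estimated correlation for lists, and each library left out in turn. A fit with the skeletal muscle level as a covariate, a fit without the 9 globin genes, and 4 further gene lists were added after the data had been seen. No other library or gene was left out.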

Results

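Tibia RNA of male Sprague Dawley rats was measured by sequencing in 3 groups of 3 libraries, called Model, GelMA and PMLGH. The title of the study names a peptide that imitates lysyl oxidase, the enzyme that starts collagen cross-linking, and bone healing in diabetes. Total counts were 34571478, 35620680 and 34571544 in Model replicates 1, 2 and 5. They were 36200746, 35816685 and 36211238 in GelMA replicates 2, 3 and 4, and 36856241, 37120627 and 37166383 in PMLGH replicates 2, 3 and 4. The groups did not overlap in total counts (exact two-sided permutation p = 0.1 for each pair, the smallest that 3 against 3 libraries allow). The labels name no batch and do not say whether other libraries were made, so a batch that coincides with the groups cannot be told apart from what the groups received in any comparison below. Model 2 stood apart from the other Model libraries, with a mean chi-square per gene of 33.0 and 27.7 against Model 1 and 5, where these had 15.7 between them. Globin genes, which encode the chains of haemoglobin, took 9.85% ± 0.29 of the counts in Model (SD, n = 3), 7.44% ± 0.50 in GelMA and 7.27% ± 0.68 in PMLGH. Transcripts of the mitochondrial genome took 5.22% ± 0.26, 5.38% ± 0.088 and 5.28% ± 0.25.

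PMLGH against Model asks which transcripts differ between tibiae of the PMLGH and the Model group. Of 16816 genes tested, 2637 rose and 1994 fell, and under upper-quartile scaling 2370 rose and 2495 fell. The number that fell was 1268 without PMLGH 3. The change was at least 2-fold for 571 of the genes that rose and 80 of those that fell, and the median size of a called change was 0.44 on the log2 scale. In 4384 of the 4631 called genes the libraries of both groups did not overlap. Among all tested genes 39.4% did not overlap, where chance gives 10% for 3 against 3. Lox, the lysyl oxidase itself, rose from 41.9 ± 1.0 CPM in Model to 117 ± 14 CPM in PMLGH, a log2 fold change of 1.48 ± 0.08 (edgeR adjusted p = 3.8e-09). Col1a1, the main chain of bone collagen, rose by 1.08 ± 0.08 (adjusted p = 1.7e-07).

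The 8 largest rises with a named gene and no overlap included 4 chemokines. Cxcl2, a chemokine that attracts neutrophils, rose from 0.0947 ± 0.12 to 18.2 ± 1.1 CPM (log2 fold change 7.51 ± 0.31, edgeR adjusted p = 3.8e-10). Without Model 2, the Model library that held most of its few counts, the value was 9.09. Arg1, the arginase of alternatively activated macrophages, rose by 6.27 ± 0.16 (adjusted p = 2.3e-12). Cxcl3, a related chemokine, rose by 6.21 ± 0.38 and by 7.38 without Model 2. Acod1, which makes itaconate in activated macrophages, rose by 5.71 ± 0.22. The monocyte chemokine Ccl7 rose by 4.68 ± 0.41. Cxcl11, a chemokine induced by interferon, rose by 4.63 ± 0.39, and by 5.81 without Model 1. Ca4, a carbonic anhydrase bound to the membrane, rose by 4.54 ± 0.44. Ctrb1, the precursor of the digestive protease chymotrypsin, had 0 counts in Model and 1.53 ± 0.77 CPM in PMLGH, at least 17.6-fold higher against the floor of 3 counts per library. Its call was lost with a robust spread (adjusted p = 0.074, with a range of 9.4e-06 to 0.074 over its alternatives).

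Among the 8 largest falls were 2 keratins. Krt5, a keratin of basal epithelial cells, had 1 count over the 3 PMLGH libraries and 268 over the Model libraries, a ratio of Model to PMLGH of 287 with a 95% counting interval of 51.1 to 11379. Without PMLGH 3 its fitted log2 fold change moved from -7.70 to -9.54. Krt12, a keratin best known from the cornea, fell by 3.65 ± 0.89 (edgeR adjusted p = 0.0068). Prss34, a serine protease that mast cells and basophils make in rodents, fell by 2.33 ± 0.37, and the related protease Prss29 fell by 2.27 ± 0.33. The zinc finger gene Zfp955a fell by 1.66 ± 0.30 and Slc7a10, an amino acid transporter, fell by 1.32 ± 0.25. Of these, Prss34, Prss29 and Zfp955a have near-identical copies and are uncertain.

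Genes of the bone matrix rose as groups. Of the lysyl oxidase and collagen cross-linking genes, 18 of 19 rose and 1 did not pass (the same adjusted over the list alone), with a median log2 fold change of 0.71 (camera adjusted p = 1.3e-14). Lum, a small proteoglycan that spaces collagen fibrils, rose by 1.43 ± 0.06, and Loxl2, a relative of Lox, by 1.09 ± 0.07. Of the collagen genes, 24 of 25 rose and 1 did not pass (the same adjusted over the list alone), with a median log2 fold change of 1.15 (camera adjusted p = 8.4e-21). They include Col15a1, a collagen of basement membranes (1.90 ± 0.07), Col12a1, which binds to fibril surfaces (1.56 ± 0.07), and Col3a1, the collagen of young and healing tissue (2.03 ± 0.09). Of the matrix proteases and their inhibitors, 19 of 23 rose and 4 did not pass (20 adjusted over the list alone), with a median log2 fold change of 1.00 (camera adjusted p = 4.1e-14). The gelatinase Mmp2 rose by 1.66 ± 0.06 and the membrane-bound collagenase Mmp14 by 1.63 ± 0.08. Among fibroblast, periosteum and tendon genes, 18 of 26 rose and 8 did not pass (21 adjusted over the list alone), with a median log2 fold change of 0.80 (camera adjusted p = 1.4e-10). Thbs2, a matrix protein of connective tissue cells, rose by 2.40 ± 0.11 and Postn, named after the periosteum, by 2.62 ± 0.13.

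The lists of osteoblasts, osteocytes and osteoclasts passed in PMLGH against Model, and the chondrocyte list did not. Of the osteoblast and mineralization genes, 18 of 24 rose, 1 fell and 5 did not pass (the same adjusted over the list alone), with a median log2 fold change of 0.70 (camera adjusted p = 1.1e-07, and adjusted p = 0.18 with an estimated correlation). Tnn, a tenascin of the periosteum, rose by 2.60 ± 0.10, Alpl, the phosphatase that bone cells use in mineralization, by 0.92 ± 0.07, and Bglap, which encodes osteocalcin, by 0.79 ± 0.10. Runx2, the transcription factor that starts the osteoblast lineage, rose by 0.27 ± 0.07 (edgeR adjusted p = 0.016). Its call was lost without Model 2, Model 5 or PMLGH 3 (adjusted p = 0.063, 0.071 and 0.097) and on both FPKM scales (0.077 and 0.073), with a range of 0.012 to 0.097 over its alternatives. Of the osteocyte genes, 5 of 10 rose and 5 did not pass (7 adjusted over the list alone), with a median log2 fold change of 0.64 (camera adjusted p = 0.0022, and adjusted p = 0.26 with an estimated correlation). Pdpn, a protein of early osteocytes, rose by 1.08 ± 0.09. Of the osteoclast genes, 12 of 18 rose, 1 fell and 5 did not pass (13 rose and 2 fell adjusted over the list alone), with a median log2 fold change of 0.53 (camera adjusted p = 7.5e-05, and adjusted p = 0.20 with an estimated correlation). Acp5, the acid phosphatase used to stain osteoclasts, rose by 0.82 ± 0.09, and Ctsk, the protease with which they break down collagen, by 0.86 ± 0.12. The chondrocyte genes did not pass: 4 of 24 rose, 5 fell and 15 did not pass (the same adjusted over the list alone), with a median of -0.03, a mean of 0.10 and a lower direction in camera (adjusted p = 0.82), while fry gave a higher one.

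Lists of signalling and of vessels passed as well. Of the TGF-beta and BMP genes, 19 of 29 rose, 1 fell and 9 did not pass (22 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.45 (camera adjusted p = 2.8e-08). Ccn1, a matrix protein induced by growth factors, rose by 1.18 ± 0.10 and the receptor Tgfbr1 by 0.67 ± 0.07. Of the Wnt genes, 15 of 33 rose and 18 did not pass (the same adjusted over the list alone), with a median log2 fold change of 0.47 (camera adjusted p = 1.1e-06). The Wnt receptor Fzd1 rose by 1.52 ± 0.12 and the Wnt antagonist Sfrp1 by 0.97 ± 0.09. Of the endothelial genes, 14 of 26 rose and 12 did not pass (17 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.31 (camera adjusted p = 6.4e-06, and adjusted p = 0.10 with an estimated correlation). Eng, an endothelial receptor of the TGF-beta family, rose by 0.52 ± 0.06 and Flt1, a receptor of VEGF, by 0.69 ± 0.08.

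Camera called several immune lists higher in PMLGH against Model. Of the pro-inflammatory cytokines and mediators, 26 of 31 rose and 5 did not pass (27 adjusted over the list alone), with a median log2 fold change of 1.70 (camera adjusted p = 3.2e-17). Nos2, the inducible nitric oxide synthase, rose by 2.56 ± 0.12 and the cytokine Il1b by 2.15 ± 0.11. Of the macrophage and monocyte genes, 19 of 25 rose, 1 fell and 5 did not pass (20 rose and 2 fell adjusted over the list alone), with a median log2 fold change of 0.49 (camera adjusted p = 2.6e-07, and adjusted p = 0.20 with an estimated correlation). Cd14, a receptor for bacterial lipopolysaccharide, rose by 1.51 ± 0.09 and Gpnmb, a glycoprotein of macrophages and osteoclasts, by 0.84 ± 0.07. Of the alternatively activated macrophage genes, 9 of 15 rose and 6 did not pass (9 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.62 (camera adjusted p = 2.0e-05). The folate receptor Folr2 rose by 1.08 ± 0.10. Of the T and NK cell genes, 14 of 28 rose and 14 did not pass (18 adjusted over the list alone), with a median log2 fold change of 0.69 (camera adjusted p = 2.6e-07, and adjusted p = 0.13 with an estimated correlation). Zap70, a kinase of the T cell receptor, rose by 1.20 ± 0.15. Of the interferon response genes, 13 of 34 rose, 3 fell and 18 did not pass (15 rose and 5 fell adjusted over the list alone), with a median log2 fold change of 0.24 (camera adjusted p = 0.010, and adjusted p = 0.56 with an estimated correlation). Gbp2, a GTPase induced by interferon, rose by 1.15 ± 0.07. Of the immediate early genes, 18 of 29 rose, 3 fell and 8 did not pass (19 rose and 4 fell adjusted over the list alone), with a median log2 fold change of 0.49 (camera adjusted p = 7.5e-05). Socs3, a brake on cytokine signalling, rose by 2.06 ± 0.09. Of the neutrophil genes, 5 of 23 rose, 1 fell and 17 did not pass (the same adjusted over the list alone), with a median log2 fold change of 0.19 (camera adjusted p = 0.042, and adjusted p = 0.70 with an estimated correlation). The gelatinase Mmp9, which neutrophils and osteoclasts make, rose by 0.53 ± 0.07. In Model 2 the mean log2 CPM was 5.82 for the macrophage list and 8.83 for the neutrophil list, against 5.51 and 8.41 in Model 1 and 5.52 and 8.55 in Model 5.

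Camera called the lists of erythroid cells, megakaryocytes and the cell cycle lower in PMLGH against Model. Of the erythroid genes, 33 of 33 fell (the same adjusted over the list alone), with a median log2 fold change of -0.46 (camera adjusted p = 1.3e-14, and adjusted p = 0.21 with an estimated correlation). Klf1, the transcription factor that switches on globin genes, fell by 0.59 ± 0.08, and Hbb-b1, a beta globin whose copies make its count uncertain, fell by 0.53 ± 0.07. Their list took 11.7% ± 0.59 of the counts in Model (SD, n = 3) and 8.83% ± 0.73 in PMLGH (exact permutation p = 0.1), and its mean log2 CPM was 9.50 in Model 2 against 9.82 and 9.76 in Model 1 and 5. Of the megakaryocyte genes, 12 of 18 fell and 6 did not pass (the same adjusted over the list alone), with a median log2 fold change of -0.28 (camera adjusted p = 1.9e-05, and adjusted p = 0.18 with an estimated correlation). Tubb1, the tubulin of platelets, fell by 0.43 ± 0.06. Of the cell cycle genes, 35 of 38 fell and 3 did not pass (36 adjusted over the list alone), with a median log2 fold change of -0.27 (camera adjusted p = 2.3e-14, and adjusted p = 0.18 with an estimated correlation). Mki67, which encodes the proliferation marker Ki-67, fell by 0.39 ± 0.07. Among B cell genes 3 rose and 2 fell of 25 (adjusted over the list alone, 3 and 1), and the list did not pass (median -0.13, camera adjusted p = 0.45).

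Skeletal muscle genes, which mark a tissue other than bone, also moved with the groups. Of the muscle genes, 31 of 40 rose and 9 did not pass (35 adjusted over the list alone), with a median log2 fold change of 0.62 (camera adjusted p = 1.1e-10, and adjusted p = 0.18 with an estimated correlation). The mean log2 CPM of the list was 4.61 ± 0.13 in PMLGH and 3.82 ± 0.18 in Model (SD, n = 3, exact permutation p = 0.1), and its members took 0.198% and 0.129% of the counts. Myh7, the myosin of slow fibres and heart, rose by 2.24 ± 0.25 and Casq2, a calcium store protein of the same fibres, by 2.07 ± 0.27. Of the adipocyte genes, 2 of 25 rose, 6 fell and 17 did not pass (2 rose and 8 fell adjusted over the list alone), with a median log2 fold change of -0.14 (camera adjusted p = 0.040, and adjusted p = 0.54 with an estimated correlation). Lpin1, a phosphatase of fat synthesis, fell by 0.49 ± 0.08.

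Camera called 4 lists of metabolism and stress in PMLGH against Model. Of the glycolysis genes, 8 of 25 rose, 2 fell and 15 did not pass (10 rose and 2 fell adjusted over the list alone), with a median log2 fold change of 0.17 (camera adjusted p = 0.0043, and adjusted p = 0.28 with an estimated correlation). The glucose transporter Slc2a1 rose by 1.43 ± 0.12. Of the hypoxia genes, 8 of 19 rose, 1 fell and 10 did not pass (10 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.28 (camera adjusted p = 2.3e-04). Hif1a, the main factor of that response, rose by 0.84 ± 0.06. Of the AGE-RAGE genes, which respond to sugar-modified proteins, 14 of 25 rose, 1 fell and 10 did not pass (16 rose and 3 fell adjusted over the list alone), with a median log2 fold change of 0.46 (camera adjusted p = 4.2e-05). The basement membrane collagen Col4a1 rose by 1.39 ± 0.07. Of the oxidative phosphorylation genes, 1 of 41 rose, 7 fell and 33 did not pass (6 fell adjusted over the list alone), with a median log2 fold change of -0.06 (camera adjusted p = 0.0037, and adjusted p = 0.38 with an estimated correlation). Cox7b, a subunit of cytochrome oxidase, fell by 0.31 ± 0.07.

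The remaining lists did not pass in PMLGH against Model. Their medians and camera adjusted p-values were 0.04 and 0.63 for mast cells (2 of 12 rose), 0.01 and 0.68 for peripheral nerve, and -0.05 and 0.46 for antioxidants. Antioxidant members moved both ways, 8 higher and 9 lower, with a mean of 0.01. For the unfolded protein response the median was 0.11 (adjusted p = 0.11, 8 of 25 rose and 3 fell). For mitochondrially encoded transcripts it was 0.02 with a lower direction in camera (adjusted p = 0.95). The nerve median was -0.01 under RLE and -0.03 under upper-quartile scaling, and the mitochondrial median -0.01 under upper-quartile scaling. Calls of 3 lists were lost when a single library was left out. The neutrophil call was lost without Model 1, Model 5, GelMA 2, PMLGH 3 and PMLGH 4 (medians 0.10, 0.14, 0.18, 0.17 and 0.12, adjusted p = 0.39, 0.11, 0.054, 0.10 and 0.24), with adjusted p of 7.3e-04 to 0.70 over its alternatives. The adipocyte call was lost without Model 5, PMLGH 2 and PMLGH 3 (medians -0.13, -0.15 and -0.13, adjusted p = 0.13, 0.085 and 0.060), with 0.0066 to 0.54 over its alternatives. The interferon call was lost without Model 2 (median 0.13, adjusted p = 0.087), with 0.0017 to 0.56 over its alternatives. Medians that kept their call but moved by over 1.5 times were -0.27 for adipocytes and -0.11 for oxidative phosphorylation without Model 2, and 0.11 for glycolysis without Model 1.

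**Figure D1:**
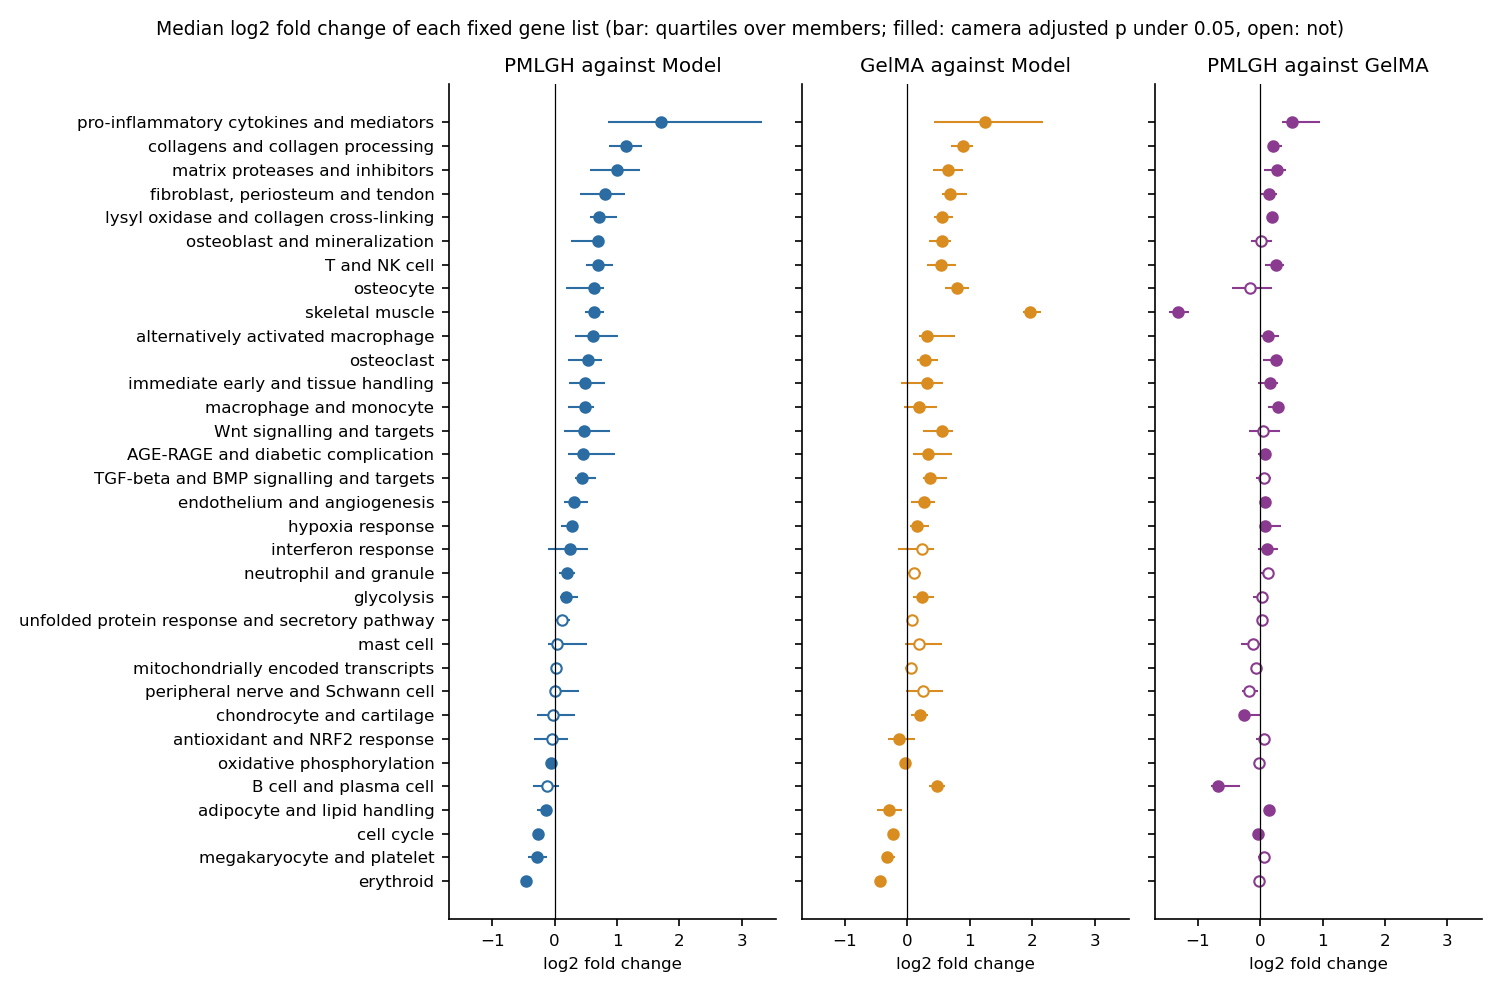
Median log2 fold change of the members of each gene list, with the range from the lower to the upper quartile of the members as lines, for the 3 comparisons. The muscle median is 1.96 in GelMA against Model and -1.31 in PMLGH against GelMA.

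GelMA against Model asks which transcripts differ between tibiae of the GelMA and the Model group. Of 16816 genes, 2143 rose and 1661 fell, with at least 2-fold changes in 524 and 66. The number that fell was 1035 without Model 1 and 1088 without Model 5, and 1107 and 1103 on the FPKM scales. The libraries of both groups did not overlap in 3634 of the 3804 called genes, and in 36.6% of all tested genes. Lox rose by 1.08 ± 0.08 to 88.7 ± 3.8 CPM (edgeR adjusted p = 1.8e-07, SE, n = 3 per group). Col1a1 rose by 0.92 ± 0.08, Bglap by 1.04 ± 0.10, Acp5 by 0.57 ± 0.09 and Ctsk by 0.49 ± 0.12. Runx2 rose by 0.26 ± 0.07 (adjusted p = 0.022), and its call was lost without Model 2, Model 5, GelMA 3 or GelMA 4 (adjusted p = 0.078, 0.085, 0.15 and 0.088), with a range of 0.016 to 0.15 over its alternatives.

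The largest rises included Cxcl2 (7.01 ± 0.32, and 8.58 without Model 2), Arg1 (5.67 ± 0.16), Acod1 (4.35 ± 0.22) and Ca4 (4.26 ± 0.44). Fcrl2, a receptor-like protein of the Fc receptor family, rose by 3.99 ± 0.18 (edgeR adjusted p = 2.7e-09). Krt1, a keratin of the outer epidermis, rose by 4.24 ± 1.06, but that rested on GelMA 4, and without it the value was 1.07 (adjusted p = 0.31, with a range of 4.7e-05 to 0.31 over its alternatives). Among the largest falls, Sirpd, a signal-regulatory protein with near-identical copies that make its count uncertain, fell by 2.98 ± 0.30 (adjusted p = 7.0e-06). Pdzk1ip1, a small membrane protein of red cell precursors and epithelia, fell by 2.32 ± 0.43. Ifit1, an antiviral protein induced by interferon, fell by 1.57 ± 0.26, and Sdsl, an enzyme that breaks down serine, fell by 1.66 ± 0.27.

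Matrix and bone genes rose in GelMA against Model. Of the lysyl oxidase and collagen cross-linking genes, 18 of 19 rose and 1 did not pass (the same adjusted over the list alone), with a median log2 fold change of 0.55 (camera adjusted p = 2.9e-12, and adjusted p = 0.054 with an estimated correlation). Plod2, which prepares collagen for cross-linking, rose by 0.64 ± 0.05 and Lum by 0.93 ± 0.06. Among collagen genes, 25 of 25 rose (the same adjusted over the list alone), with a median log2 fold change of 0.89 (camera adjusted p = 1.2e-20, and adjusted p = 0.064 with an estimated correlation). Col15a1 rose by 1.39 ± 0.07 and Col3a1 by 1.51 ± 0.09. Among matrix proteases, 17 of 23 rose and 6 did not pass (the same adjusted over the list alone), with a median log2 fold change of 0.64 (camera adjusted p = 1.2e-11). The stromelysin Mmp3 rose by 2.50 ± 0.11. Among fibroblast and periosteum genes, 19 of 26 rose and 7 did not pass (20 adjusted over the list alone), with a median log2 fold change of 0.68 (camera adjusted p = 3.7e-10, and adjusted p = 0.054 with an estimated correlation). Thbs2 rose by 1.65 ± 0.11 and Postn by 1.72 ± 0.12. For TGF-beta and BMP genes, 18 of 29 rose, 1 fell and 10 did not pass (the same adjusted over the list alone), with a median log2 fold change of 0.36 (camera adjusted p = 1.6e-07). Ltbp2, a protein of elastic microfibrils, rose by 1.02 ± 0.10. For Wnt genes, 13 of 33 rose and 20 did not pass (16 adjusted over the list alone), with a median log2 fold change of 0.55 (camera adjusted p = 1.2e-07). Ccn4, a target of Wnt signalling in bone, rose by 0.73 ± 0.08.

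Among osteoblast genes, 18 of 24 rose and 6 did not pass (19 adjusted over the list alone), with a median log2 fold change of 0.56 (camera adjusted p = 2.3e-09, and adjusted p = 0.15 with an estimated correlation). Tnn rose by 1.92 ± 0.10 and Alpl by 0.70 ± 0.07. Among osteocyte genes, 8 of 10 rose and 2 did not pass (the same adjusted over the list alone), with a median log2 fold change of 0.79 (camera adjusted p = 6.0e-06, and adjusted p = 0.15 with an estimated correlation). Mepe, a phosphoprotein of osteocytes, rose by 0.82 ± 0.09, and Sost, which encodes the bone formation inhibitor sclerostin, by 0.66 ± 0.08. Among osteoclast genes, 6 of 18 rose, 1 fell and 11 did not pass (14 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.27 (camera adjusted p = 0.010, and adjusted p = 0.36 with an estimated correlation). Among chondrocyte genes, 6 of 24 rose, 2 fell and 16 did not pass (the same adjusted over the list alone), with a median log2 fold change of 0.20 (camera adjusted p = 0.049, and adjusted p = 0.41 with an estimated correlation). Col11a1, a cartilage collagen that also occurs in bone, rose by 0.81 ± 0.07. Among endothelial genes, 12 of 26 rose and 14 did not pass (13 adjusted over the list alone), with a median log2 fold change of 0.26 (camera adjusted p = 4.1e-04, and adjusted p = 0.18 with an estimated correlation). Pecam1, an adhesion protein of endothelial cells, rose by 0.45 ± 0.06.

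Camera called several immune lists higher in GelMA against Model. For pro-inflammatory genes, 19 of 31 rose and 12 did not pass (23 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 1.25 (camera adjusted p = 7.2e-11, and adjusted p = 0.054 with an estimated correlation). The median was 1.14 with Ccl20, a chemokine with 0 counts in Model, at its bound. Nos2 rose by 2.05 ± 0.11 and Il1b by 1.64 ± 0.11. For macrophage genes, 8 of 25 rose, 2 fell and 15 did not pass (10 rose and 2 fell adjusted over the list alone), with a median log2 fold change of 0.18 (camera adjusted p = 0.049, and adjusted p = 0.59 with an estimated correlation). Gpnmb rose by 0.90 ± 0.07, while Spic, a factor of iron-recycling macrophages, fell by 0.54 ± 0.11. For alternatively activated macrophage genes, 9 of 15 rose and 6 did not pass (10 adjusted over the list alone), with a median log2 fold change of 0.32 (camera adjusted p = 5.7e-05, and adjusted p = 0.054 with an estimated correlation). Il1rn, the natural blocker of interleukin-1, rose by 0.79 ± 0.11. For B cell genes, 14 of 25 rose and 11 did not pass (18 adjusted over the list alone), with a median log2 fold change of 0.47 (camera adjusted p = 5.5e-05, and adjusted p = 0.34 with an estimated correlation). Sdc1, a surface marker of plasma cells, rose by 0.81 ± 0.07, and Mzb1, which plasma cells need to fold antibodies, by 1.16 ± 0.18. The mean log2 CPM of the B cell list was 4.82 in Model 2 against 4.38 and 4.32 in Model 1 and 5. For T and NK cell genes, 11 of 28 rose and 17 did not pass (15 adjusted over the list alone), with a median log2 fold change of 0.53 (camera adjusted p = 2.6e-05, and adjusted p = 0.18 with an estimated correlation). Zap70 rose by 0.90 ± 0.15. For immediate early genes, 12 of 29 rose, 5 fell and 12 did not pass (14 rose and 5 fell adjusted over the list alone), with a median log2 fold change of 0.31 (camera adjusted p = 0.035, and adjusted p = 0.18 with an estimated correlation). Socs3 rose by 1.48 ± 0.09.

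The same 3 lists were called lower in GelMA against Model. Of the erythroid genes, 32 of 33 fell and 1 did not pass (the same adjusted over the list alone), with a median log2 fold change of -0.44 (camera adjusted p = 4.7e-16, and adjusted p = 0.18 with an estimated correlation). Klf1 fell by 0.58 ± 0.08 and Epb41, a protein of the red cell skeleton, fell by 0.44 ± 0.06. Their list took 9.01% ± 0.50 of the counts in GelMA (SD, n = 3). Among megakaryocyte genes, 14 of 18 fell and 4 did not pass (15 adjusted over the list alone), with a median log2 fold change of -0.33 (camera adjusted p = 1.2e-09, and adjusted p = 0.073 with an estimated correlation). Pf4, a chemokine of platelets, fell by 0.39 ± 0.06. Among cell cycle genes, 26 of 38 fell and 12 did not pass (35 adjusted over the list alone), with a median log2 fold change of -0.23 (camera adjusted p = 3.3e-13, and adjusted p = 0.18 with an estimated correlation). Ccne2, the cyclin that opens DNA synthesis, fell by 0.48 ± 0.08.

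Skeletal muscle genes changed most as a list. Of its members, 40 of 40 rose (the same adjusted over the list alone), with a median log2 fold change of 1.96 (camera adjusted p = 1.5e-31, and adjusted p = 0.054 with an estimated correlation). The mean log2 CPM of the list was 5.83 ± 0.18 in GelMA and 3.82 ± 0.18 in Model (SD, n = 3, exact permutation p = 0.1), and its share of the counts was 0.530% against 0.129%. Ryr1, the calcium channel of muscle, rose by 1.86 ± 0.10 and Mybpc1, a myosin-binding protein, by 2.48 ± 0.14. Among glycolysis genes, 10 of 25 rose, 1 fell and 14 did not pass (the same adjusted over the list alone), with a median log2 fold change of 0.24 (camera adjusted p = 6.4e-04, and adjusted p = 0.19 with an estimated correlation). The muscle enzyme Pgam2 rose by 2.11 ± 0.23. Among oxidative phosphorylation genes, 2 of 41 rose, 3 fell and 36 did not pass (the same adjusted over the list alone), with a median log2 fold change of -0.04 (camera adjusted p = 0.017, and adjusted p = 0.42 with an estimated correlation), a lower direction in camera and a mean of 0.04. Cox8b, a cytochrome oxidase subunit of muscle, rose by 2.61 ± 0.33, and Cox7b fell by 0.33 ± 0.07. Among adipocyte genes, 1 of 25 rose, 12 fell and 12 did not pass (1 rose and 15 fell adjusted over the list alone), with a median log2 fold change of -0.30 (camera adjusted p = 1.9e-04, and adjusted p = 0.25 with an estimated correlation). Fabp4, the fatty acid carrier of adipocytes, fell by 0.67 ± 0.08.

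Of the antioxidant genes, 2 of 30 rose, 10 fell and 18 did not pass (4 rose and 14 fell adjusted over the list alone), with a median log2 fold change of -0.13 (camera adjusted p = 0.041, and adjusted p = 0.18 with an estimated correlation). Sod2, the mitochondrial superoxide dismutase, rose by 0.60 ± 0.06 and Gsta4, a glutathione transferase, fell by 0.45 ± 0.09. Among AGE-RAGE genes, 11 of 25 rose, 2 fell and 12 did not pass (12 rose and 2 fell adjusted over the list alone), with a median log2 fold change of 0.33 (camera adjusted p = 0.0010, and adjusted p = 0.073 with an estimated correlation). Col4a1 rose by 0.88 ± 0.07. Among hypoxia genes, 6 of 19 rose, 2 fell and 11 did not pass (7 rose and 2 fell adjusted over the list alone), with a median log2 fold change of 0.16 (camera adjusted p = 0.037, and adjusted p = 0.15 with an estimated correlation). Ddit4, a stress-induced inhibitor of mTOR, fell by 0.99 ± 0.10, and Ndrg1, induced by low oxygen, rose by 0.50 ± 0.05. The medians and camera adjusted p-values of lists that did not pass were 0.10 and 0.33 for neutrophils, 0.19 and 0.19 for mast cells, and 0.26 and 0.18 for nerve. They were 0.23 and 0.16 for interferon response, where 10 of 34 rose and 4 fell. They were 0.06 and 0.35 for mitochondrially encoded transcripts, and 0.07 and 0.33 for the unfolded protein response.

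Several list calls in GelMA against Model rested on single libraries. The osteoclast call was lost without Model 5 (median 0.19, adjusted p = 0.063), and adjusted p ran over 0.0022 to 0.36 in its alternatives. The chondrocyte call was lost without Model 2, Model 5, GelMA 3, GelMA 4 and PMLGH 4 (medians 0.16, 0.17, 0.17, 0.20 and 0.20, adjusted p = 0.25, 0.065, 0.13, 0.050 and 0.053), and under RLE scaling (adjusted p = 0.051). The macrophage call was lost without Model 1, Model 5, GelMA 2, GelMA 4 and PMLGH 4 (medians 0.11, 0.15, 0.15, 0.15 and 0.18, adjusted p = 0.22, 0.16, 0.12, 0.086 and 0.052), under RLE scaling (0.051) and with no filter on low counts (0.053). The ranges over alternatives were 0.0089 to 0.41 for chondrocytes and 0.0011 to 0.59 for macrophages. The antioxidant call was lost without Model 5 and GelMA 4 (medians -0.12 and -0.14, adjusted p = 0.096 and 0.060), with 0.023 to 0.18 over its alternatives. The immediate early call was lost without GelMA 2 and PMLGH 4 (medians 0.29 and 0.31, adjusted p = 0.11 and 0.051), with 4.2e-04 to 0.18, and the hypoxia call without Model 5, GelMA 2 and GelMA 3 (medians 0.12, 0.15 and 0.15, adjusted p = 0.058, 0.065 and 0.051), with 3.1e-05 to 0.15. The macrophage median was 0.28 without Model 2, and the oxidative phosphorylation median was -0.09, -0.08 and -0.07 without Model 2, GelMA 2 and GelMA 4, and -0.07 with no filter on low counts.

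**Figure D2:**
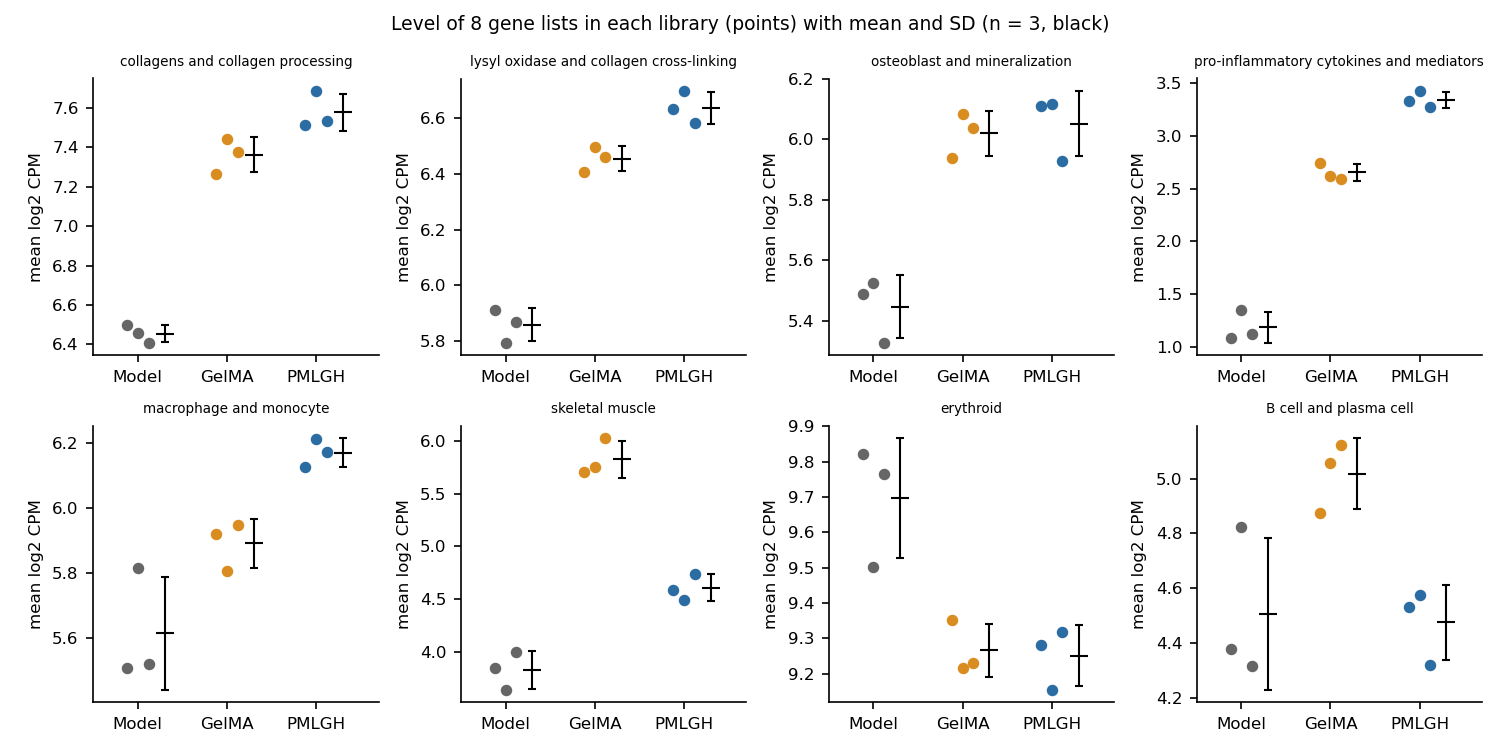
Mean log2 CPM of the members of 8 gene lists in each of the 9 libraries (points), with group means and SD, n = 3. The muscle list lies between 5.70 and 6.03 in GelMA libraries, between 4.49 and 4.74 in PMLGH and between 3.64 and 4.00 in Model.

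PMLGH against GelMA asks which transcripts differ between both of these groups. Of 16816 genes, 303 rose and 275 fell, and 26 and 112 of them changed at least 2-fold. Under upper-quartile scaling 276 rose and 306 fell. The libraries did not overlap in 576 of the 578 called genes, and in 23.7% of all tested genes. Leaving out 1 library moved the count of 578 to 1050 without Model 2, 338 without GelMA 3, 328 without GelMA 4, 373 without PMLGH 2, 303 without PMLGH 3 and 381 without PMLGH 4. Lox rose by 0.40 ± 0.07, from 88.7 ± 3.8 to 117 ± 14 CPM (edgeR adjusted p = 0.0068). The Lox call was lost without PMLGH 3 (log2 fold change 0.33, adjusted p = 0.054) and on both FPKM scales (adjusted p = 0.068 and 0.068), with a range of 1.0e-04 to 0.068 over its alternatives. Col1a1 (0.17 ± 0.08, adjusted p = 0.33), Runx2 (0.01 ± 0.07, 0.98), Bglap (-0.24 ± 0.10, 0.23), Acp5 (0.24 ± 0.09, 0.21) and Ctsk (0.38 ± 0.12, 0.10) did not pass.

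Among the 8 largest rises were Sirpd and Gal. Sirpd, whose count is uncertain because of its copies, rose by 2.91 ± 0.30 (edgeR adjusted p = 5.6e-05), and Gal, which encodes the neuropeptide galanin, by 1.83 ± 0.30 (adjusted p = 0.0022). Saal1, named for its likeness to serum amyloid A, rose by 1.62 ± 0.15. Fosb, an immediate early transcription factor, rose by 1.49 ± 0.19, the cytokine Il1a by 1.45 ± 0.24 and Cxcl10, a chemokine for T cells, by 1.40 ± 0.16. Apoc1, an apolipoprotein of macrophages and liver, rose by 1.72 ± 0.35 (adjusted p = 0.011). That call was lost without GelMA 2, GelMA 3 or PMLGH 3 (adjusted p = 0.051, 0.062 and 0.063) and on the FPKM scale with a pseudocount of 0.1 (0.053), with a range of 3.9e-05 to 0.063 over its alternatives.

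Among the 8 largest falls were Krt5 and genes of muscle. Krt5 had 203 counts over the GelMA libraries and 1 over the PMLGH libraries, a ratio of 205 with a 95% counting interval of 36.4 to 8136. In GelMA 3 it was as low, at 0.0547 CPM against 2.90 in GelMA 2 and 2.59 in GelMA 4, and without PMLGH 3 its fitted log2 fold change moved from -7.21 to -9.06. Its call was lost with a robust spread and on both FPKM scales (adjusted p = 0.063, 0.17 and 0.13), with a range of 2.8e-06 to 0.17 over its alternatives. Mylk4, a myosin light chain kinase, fell by 2.77 ± 0.25 (edgeR adjusted p = 1.6e-05), Myoz3, a protein of the muscle Z disc, fell by 2.32 ± 0.26, and Ckmt2, the mitochondrial creatine kinase of muscle, fell by 2.02 ± 0.20. Of the skeletal muscle list, 35 of 40 fell and 5 did not pass (37 adjusted over the list alone), with a median log2 fold change of -1.31 (camera adjusted p = 2.0e-43, and adjusted p = 0.094 with an estimated correlation). The list took 0.198% ± 0.027 of the counts in PMLGH and 0.530% ± 0.070 in GelMA (SD, n = 3). Ryr1 fell by 1.20 ± 0.09 and Mybpc1 fell by 1.63 ± 0.13. Of the 112 genes at least 2-fold lower in PMLGH, 33 belong to the muscle list.

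Part of the matrix genes rose further in PMLGH than in GelMA. Of the lysyl oxidase and collagen cross-linking genes, 5 of 19 rose and 14 did not pass (9 adjusted over the list alone), with a median log2 fold change of 0.18 (camera adjusted p = 1.4e-07, and adjusted p = 0.17 with an estimated correlation). Lum rose by 0.50 ± 0.06. Among collagen genes, 7 of 25 rose and 18 did not pass (11 adjusted over the list alone), with a median log2 fold change of 0.20 (camera adjusted p = 1.4e-07, and adjusted p = 0.26 with an estimated correlation). Col12a1 rose by 0.58 ± 0.07, Col15a1 by 0.50 ± 0.07 and Col3a1 by 0.52 ± 0.09. Among matrix proteases, 6 of 23 rose and 17 did not pass (12 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.27 (camera adjusted p = 1.1e-05, and adjusted p = 0.12 with an estimated correlation). Adamts1, a protease of proteoglycans, rose by 0.79 ± 0.10 and Timp1, an inhibitor of matrix proteases, by 0.65 ± 0.09. Among fibroblast and periosteum genes, 3 of 26 rose, 1 fell and 22 did not pass (5 rose and 2 fell adjusted over the list alone), with a median log2 fold change of 0.14 (camera adjusted p = 0.0074, and adjusted p = 0.32 with an estimated correlation). Postn rose by 0.90 ± 0.12 and Dpp4, a peptidase on fibroblast precursors, fell by 0.62 ± 0.12. Among osteoclast genes, 3 of 18 rose, 1 fell and 14 did not pass (11 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.26 (camera adjusted p = 1.3e-04, and adjusted p = 0.26 with an estimated correlation). Jdp2, a factor of osteoclast formation, rose by 0.50 ± 0.08. Among chondrocyte genes, 2 of 24 fell and 22 did not pass (10 adjusted over the list alone), with a median log2 fold change of -0.25 (camera adjusted p = 0.0025, and adjusted p = 0.28 with an estimated correlation). Prg4, the lubricating protein of joint surfaces, fell by 0.59 ± 0.10.

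Camera also called several immune lists in PMLGH against GelMA, the B cell list as lower and the others as higher. For pro-inflammatory genes, 12 of 31 rose and 19 did not pass (22 adjusted over the list alone), with a median log2 fold change of 0.51 (camera adjusted p = 1.3e-14, and adjusted p = 0.094 with an estimated correlation). Ccl3, a chemokine of macrophages, rose by 0.89 ± 0.12 and the monocyte chemokine Ccl2 by 1.23 ± 0.19. For macrophage genes, 9 of 25 rose and 16 did not pass (16 adjusted over the list alone), with a median log2 fold change of 0.29 (camera adjusted p = 4.0e-09, and adjusted p = 0.26 with an estimated correlation). Cd14 rose by 0.67 ± 0.09 and Adgre1, the antigen F4/80, by 0.64 ± 0.10. For alternatively activated macrophage genes, 1 of 15 rose and 14 did not pass (4 adjusted over the list alone), with a median log2 fold change of 0.13 (camera adjusted p = 0.018, and adjusted p = 0.23 with an estimated correlation). Arg1 rose by 0.60 ± 0.10. For T and NK cell genes, 0 of 28 passed (the same adjusted over the list alone), with a median log2 fold change of 0.26 (camera adjusted p = 0.0084, and adjusted p = 0.42 with an estimated correlation). For B cell genes, 1 of 25 rose, 13 fell and 11 did not pass (1 rose and 17 fell adjusted over the list alone), with a median log2 fold change of -0.67 (camera adjusted p = 4.0e-09, and adjusted p = 0.26 with an estimated correlation). Pax5, the factor that holds B cell identity, fell by 0.86 ± 0.14, while Sdc1 rose by 0.56 ± 0.07. For interferon response genes, 3 of 34 rose and 31 did not pass (4 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.11 (camera adjusted p = 0.0041, and adjusted p = 0.51 with an estimated correlation). Gbp2 rose by 0.56 ± 0.07. For immediate early genes, 5 of 29 rose, 1 fell and 23 did not pass (7 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.16 (camera adjusted p = 0.0041, and adjusted p = 0.17 with an estimated correlation). Fos, a factor induced within minutes of stimulation, rose by 1.20 ± 0.13 and Socs3 by 0.58 ± 0.08.

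Other lists that passed in PMLGH against GelMA had few called members. For endothelial genes, 1 of 26 rose and 25 did not pass (3 adjusted over the list alone), with a median log2 fold change of 0.07 (camera adjusted p = 0.028, and adjusted p = 0.40 with an estimated correlation). For adipocyte genes, 1 of 25 rose and 24 did not pass (the same adjusted over the list alone), with a median log2 fold change of 0.14 (camera adjusted p = 0.0074, and adjusted p = 0.46 with an estimated correlation). For AGE-RAGE genes, 4 of 25 rose and 21 did not pass (the same adjusted over the list alone), with a median log2 fold change of 0.08 (camera adjusted p = 0.0051, and adjusted p = 0.17 with an estimated correlation). Col4a1 rose by 0.51 ± 0.07. For hypoxia genes, 4 of 19 rose and 15 did not pass (5 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.07 (camera adjusted p = 0.0051, and adjusted p = 0.13 with an estimated correlation). Pfkfb3, an activator of glycolysis, rose by 0.47 ± 0.06, Hif1a by 0.42 ± 0.06 and Ddit4 by 0.66 ± 0.10. For cell cycle genes, 0 of 38 passed (the same adjusted over the list alone), with a median log2 fold change of -0.04 (camera adjusted p = 0.029, and adjusted p = 0.65 with an estimated correlation).

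The osteoblast list did not pass in PMLGH against GelMA: 2 of 24 rose and 22 did not pass (4 rose and 2 fell adjusted over the list alone), with a median log2 fold change of 0.01 (camera adjusted p = 0.59). The osteoblast median was -0.01 under upper-quartile scaling. Among osteocyte genes, 3 of 10 fell and 7 did not pass (1 rose and 3 fell adjusted over the list alone), with a median log2 fold change of -0.16 (camera adjusted p = 0.080). Medians and camera adjusted p-values of other lists that did not pass were 0.07 and 0.054 for TGF-beta and BMP (5 of 29 rose), 0.04 and 0.21 for Wnt, and 0.12 and 0.088 for neutrophils. They were -0.02 and 0.50 for erythroid cells (0 rose and 0 fell), 0.07 and 0.088 for megakaryocytes, -0.12 and 0.24 for mast cells, and -0.17 and 0.088 for nerve. For antioxidants they were 0.06 and 0.088, for oxidative phosphorylation -0.01 and 0.15, for mitochondrially encoded transcripts -0.07 and 0.11, and for the unfolded protein response 0.03 and 0.14. Glycolysis genes had a median of 0.04, a mean of -0.07 and a lower direction in camera (adjusted p = 0.65). The endothelial call was lost without GelMA 2, PMLGH 3 and PMLGH 4 (medians 0.05, 0.09 and 0.07, adjusted p = 0.20, 0.055 and 0.069), the fibroblast call without PMLGH 3 (median 0.07, adjusted p = 0.074), and the interferon call without GelMA 3 (median 0.01, adjusted p = 0.17). The adipocyte call was lost without GelMA 2 (median 0.14, adjusted p = 0.21) and the cell cycle call without GelMA 2 and PMLGH 3 (medians -0.02 and -0.01, adjusted p = 0.38 and 0.43). Over all alternatives adjusted p ran over 0.012 to 0.40, 0.0020 to 0.32, 3.0e-09 to 0.51, 2.9e-04 to 0.46 and 0.0042 to 0.65 in that order. Medians that kept their call but moved by over 1.5 times were 0.06 and 0.29 for interferon without GelMA 2 and 4, -0.07 and -0.06 for the cell cycle without GelMA 4 and PMLGH 2, 0.09 for adipocytes without PMLGH 4, 0.12 for hypoxia without GelMA 4, and 0.11 for immediate early genes without GelMA 3.

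**Figure D3:**
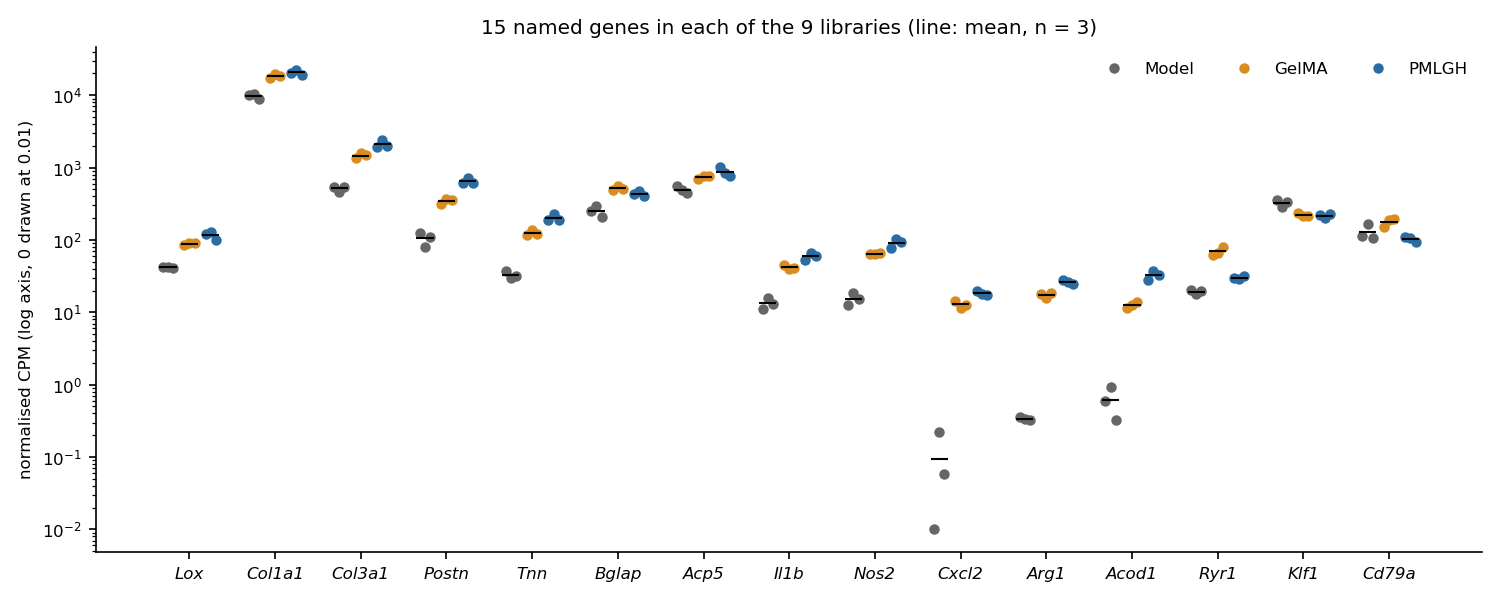
CPM of 15 named genes in each of the 9 libraries (points) on a log axis, with group means, n = 3 per group. Lox lies at 41.9 ± 1.0 CPM in Model, 88.7 ± 3.8 in GelMA and 117 ± 14 in PMLGH (mean ± SD).

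PMLGH and GelMA were both set against the same Model libraries, so their changes were compared with each other. A total of 1622 genes rose in both comparisons against Model, where independent lists would share 336, and 1270 fell in both, against 197. The last count was 728 without Model 1, 802 without Model 5 and 2035 without Model 2. Only 4 genes (C1qc, and Tmem176a, Ldhb and LOC120100912, which were picked after their values were seen) passed in opposite directions. The log2 fold changes of all 16816 genes correlated with r = 0.73 across genes, which are not independent replicates, and 80.2% had the same sign. In 20 simulations with no group effect and shared controls, with a mean of 16313 genes tested, r averaged 0.50 and 66.8% had the same sign, and 0 genes were called in both. Each simulated comparison called a mean of only 0.2 to 0.3 genes per direction. An overlap of 0 was therefore near certain and is no baseline for the number of shared calls. The covariance was 0.237 against 0.0354 in the simulations. The controls were not split between the comparisons, since with 3 Model libraries a split would leave a comparison with a single control library.

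**Figure D4:**
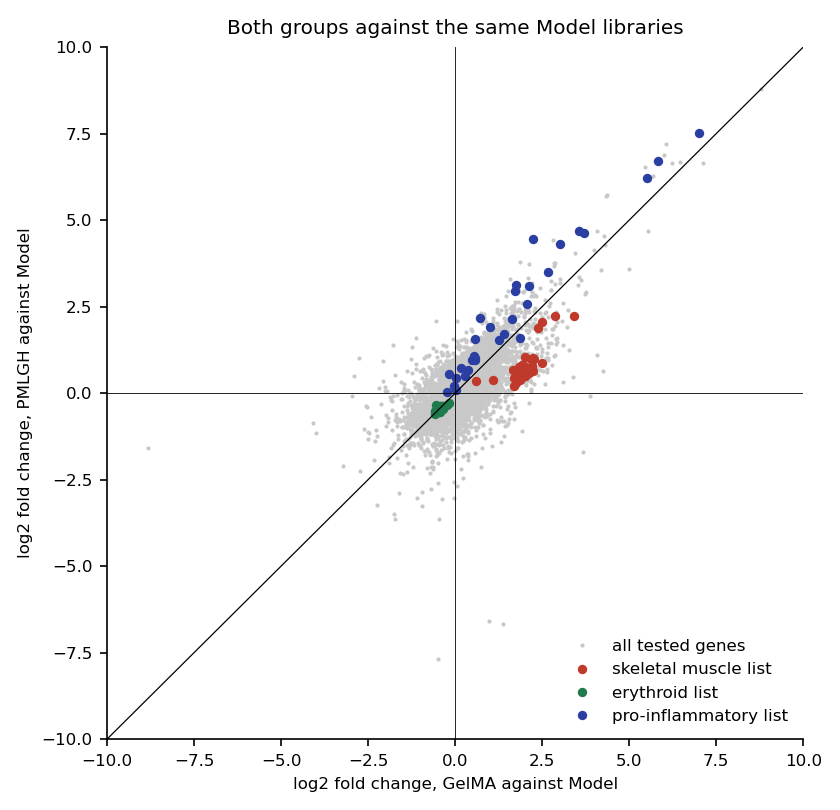
Log2 fold change of each tested gene in GelMA against Model (horizontal axis) and in PMLGH against Model (vertical axis), with members of the skeletal muscle, erythroid and pro-inflammatory lists in colour. In all, 2892 genes passed in the same direction in both and 4 in opposite directions.

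Across the 33 lists, camera called 26 in PMLGH against Model (21 higher and 5 lower), 27 in GelMA against Model (21 and 6) and 19 in PMLGH against GelMA (15 and 4). With an estimated correlation 11, 3 and 0 were called, and fry called 25, 26 and 12. The 11 are the lists of lysyl oxidase and collagen cross-linking, collagens, matrix proteases, TGF-beta and BMP, Wnt, and fibroblasts and periosteum. Also among them are alternatively activated macrophages, pro-inflammatory mediators, AGE-RAGE, immediate early genes and hypoxia. The 3 are the matrix protease, TGF-beta and BMP, and Wnt lists. Under RLE or upper-quartile scaling the median over all genes moved by at most 0.04 on the log2 scale in any comparison.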

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

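The test of the marrow share, the fit without globin genes and the choice of the 3 patterns below came only after the results were seen, while the other tests were planned.

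The next results are given because the direct test of PMLGH against GelMA passed while, against Model, either a single group passed or both passed in opposite directions. The medians below are for PMLGH against Model, GelMA against Model and PMLGH against GelMA, in that order, with camera adjusted p. The B cell list had -0.13 (adjusted p = 0.45), 0.47 (adjusted p = 5.5e-05) and -0.67 (adjusted p = 4.0e-09), and its last 2 calls are lost with an estimated correlation (adjusted p = 0.34 and 0.26). The chondrocyte list had -0.03 (adjusted p = 0.82), 0.20 (adjusted p = 0.049) and -0.25 (adjusted p = 0.0025), and its last 2 calls are lost with an estimated correlation (adjusted p = 0.41 and 0.28). Its middle call was lost without Model 2, Model 5, GelMA 3, GelMA 4 and PMLGH 4 (adjusted p = 0.25, 0.065, 0.13, 0.050 and 0.053). The interferon list had 0.24 (adjusted p = 0.010), 0.23 (adjusted p = 0.16) and 0.11 (adjusted p = 0.0041), and its first and last calls are lost with an estimated correlation (adjusted p = 0.56 and 0.51). Its first call was lost without Model 2 (median 0.13, adjusted p = 0.087) and its last without GelMA 3 (median 0.01, adjusted p = 0.17).

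The 4 genes that passed in opposite directions against Model also passed directly, and all but C1qc were chosen after their values were seen and were not run under the alternatives. In the same order of comparisons, C1qc, a chain of the first complement component made by macrophages, had log2 fold changes of 0.17, -0.19 and 0.36 (edgeR adjusted p = 0.0011 for the last, which passed in every alternative run for it). Tmem176a, a membrane protein of myeloid cells, had 0.30, -0.37 and 0.67 (adjusted p = 8.6e-05). Ldhb, a lactate dehydrogenase subunit of heart and slow muscle, had -0.46, 0.49 and -0.95 (adjusted p = 4.7e-04). The unnamed locus LOC120100912 had -0.62, 0.66 and -1.28 (adjusted p = 0.0016).

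Skeletal muscle transcripts were higher in GelMA libraries than in Model and PMLGH libraries, with Acta1 at 203 ± 39 CPM in Model, 881 ± 107 in GelMA and 306 ± 55 in PMLGH (SD, n = 3), and Myh4 at 131 ± 30, 515 ± 59 and 225 ± 32, although the list's calls are lost with an estimated correlation (camera adjusted p = 0.054 in GelMA against Model and 0.094 in PMLGH against GelMA). Scaling is argued against, since RLE and upper-quartile scaling moved the list median in PMLGH against GelMA by at most 0.0189. A candidate explanation is muscle tissue carried into the samples: the 31 members with at least 10 CPM had an interquartile range of 0.255 around a median of -1.39 in that comparison, all 31 below 0, and of all 40 members 37 had at least 1 CPM in Model too and 0 are in another list. The 9 members under 10 CPM were left out of that test, and 5 of them, all of slow fibres, had only -0.24 to -0.69, while the quartiles over all 40 were -1.45 to -1.14, so the abundant members moved together and these 5 less. Whether the muscle was taken along at dissection or lay in the healing tissue, and whether what the groups received changed it, stays open and untested.

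Erythroid transcripts were lower in PMLGH and in GelMA than in Model, with medians of -0.46 and -0.44, whose calls are lost with an estimated correlation (camera adjusted p = 0.21 and 0.18). A smaller share of whole marrow as the only change is argued against, because the neutrophil median lay above the erythroid median by 0.647 in PMLGH and 0.539 in GelMA, where the members' interquartile half-ranges were 0.101 to 0.124 and 0.0590 to 0.0617, and the B cell median by 0.329 and 0.906 (half-ranges 0.205 and 0.127), although the megakaryocyte median lay above it by only 0.174 and 0.101. Without globin genes 28 of 28 and 27 of 27 other members called lower stayed so (100%). Their medians were -0.46 and -0.48 before and after in PMLGH and -0.43 and -0.45 in GelMA. TMM scaling already limits the weight of a few abundant genes, so this outcome was largely fixed in advance and decides nothing. The direction argues against globin genes taking a large part of the counts. Their share was 9.85% in Model, 7.44% in GelMA and 7.27% in PMLGH. A larger globin share would lower other transcripts in Model, not in PMLGH or GelMA. A change in red cell precursors, a different content of blood, or white cells entering while marrow was lost could each remain, and what the groups received was not tested as their origin.

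Pro-inflammatory transcripts were higher in PMLGH than in GelMA libraries, with a median of 0.51, a call that is lost with an estimated correlation (camera adjusted p = 0.094). Less muscle RNA in PMLGH raising all others is argued against, since the drop in the share of the muscle list allows a rise of only 0.00480, although that list holds only part of the RNA of muscle. Tissue handling cannot be told apart from what the groups received: within groups the inflammatory and immediate early levels had r = -0.031 (exact permutation p = 0.968 over 216 rearrangements of 9 libraries, rho = -0.15, p = 0.833, r = 0.04 without the 2 farthest libraries). Leaving out 1 library gave r from -0.25 to 0.45, so the value near 0 excludes no link, and between groups both levels moved together. A stronger inflammatory response in PMLGH may also account for it and was not tested apart from handling.

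The 6 libraries of each comparison can be split in 10 ways, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes: 4631, 3804 and 578 in PMLGH against Model, GelMA against Model and PMLGH against GelMA, where the highest count of the other splits was 1, 0 and 1. All splits were tested with edgeR at adjusted p under 0.05. Every other split puts libraries of both groups on each side, so any group difference adds to its spread and lowers its count. These counts therefore cannot decide whether the groups differ by chance.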

How the results depend on the processing

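The fits with the skeletal muscle level as a covariate and without globin genes, and the alternatives for the level of the muscle list, were chosen after the data had been seen, and all others were planned.

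The counts of 4631 genes in PMLGH against Model and 3804 in GelMA against Model stayed within 1.5 times themselves in most alternatives. The 578 in PMLGH against GelMA often did not (303 to 1050 without 1 library). In all, 120 of 141 counts and muscle levels stayed within that bound or, for levels, 1 SD. With the muscle level as a covariate the counts were 892, 7 and 3, of which 823, 5 and 1 were called without it. Of the variance in muscle level 97.5% lies between groups, so this covariate takes away most of what separates them. A 2-fold minimum by construction lowered them to 651, 590 and 138, and with unadjusted p gave 848 and 839 against Model. In PMLGH against GelMA, its 6 libraries alone gave 1059 (574 of the 578 kept). Without Model 2, 1 or 5 it was 1050, 631 or 614, so that rise came mostly with Model 2. Limma on log2 FPKM (pseudocount 0.1) gave 384 (348 kept) and leaving out PMLGH 3 gave 303. Why these fell was not tested. Without globin genes the counts were 4721, 3858 and 593.

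With the replicate number as a block, PMLGH against GelMA had 1037 genes (573 of the 578 kept) and 20 lists in place of 19. Same-numbered libraries did not deviate together (correlations 0.014, 0.027 and -0.0083), and not every library correlated best with its own number. With so few libraries this cannot show whether a shared number marks a batch or another link, which the labels do not state. No paired analysis was possible for the comparisons against Model because Model shares only number 2 with the other groups.

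With the inter-gene correlation estimated, camera called 11, 3 and 0 of 33 lists in place of 26, 27 and 19. Beside that 0, fry called 12, and edgeR gave 2625 genes at unadjusted p under 0.05. The estimated correlation allows for members that vary together and so by construction lowers the number of calls where they do, while the cause of the lower count with fry was not tested. The direction turned for 2 results that had not passed in PMLGH against GelMA. Runx2, at 0.01, was -0.012 under upper-quartile scaling, -0.015 and -0.018 in limma on log2 FPKM with pseudocounts of 1 and 0.1, and -0.062 to 0.060 with 1 library left out. The osteoblast list, at 0.01, ran from -0.029 to 0.083 with 1 library left out, and its camera direction turned without GelMA 2, PMLGH 2 or PMLGH 3. The cause was not tested.

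Over all named genes and alternatives, 6237 of 6455 values kept direction and side of the threshold, 135 kept direction but no longer passed, 78 came to pass and 5 turned. For lists 858 of 969 did, 108 no longer passed and 3 turned. No value could be had for Hbb-b1 and Hbb-bs without globin genes, for Krt1 in GelMA against Model with DESeq2, or for Krt5 in PMLGH against GelMA with only the 6 libraries compared. The camera tests of lists were not run under upper-quartile scaling, the 10-count filter, only the 6 libraries compared, a robust spread, FPKM or DESeq2, and the 969 values cover the lists that camera called and the osteoblast list in PMLGH against GelMA. Depth limits the folds of genes with few counts: for Krt5, with 1 count in PMLGH, the counting interval of the ratio to Model spans 51.1 to 11379. In simulated data 59.7% to 67.2% of 1.5-fold changes were recovered, so a gene that did not pass is not shown to be unchanged.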

Other observations

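The 4 gene lists below, the genes taken from them and Slpi were chosen after their values were seen, so the tests of those lists followed the result and are not independent evidence of their direction. They were not run with a library left out. The slow-fibre genes at the end were picked in the same way from a list fixed earlier.

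Complement genes were tested as 1 list. Of 24 tested, 16 rose and 8 did not pass in PMLGH against Model (median log2 fold change 0.40, camera adjusted p = 8.6e-06). In GelMA against Model 11 rose, 2 (C1qc -0.19 and Cfd -0.27) fell and 11 did not pass (median 0.32, adjusted p = 0.0087, and adjusted p = 0.058 with an estimated correlation), and in PMLGH against GelMA 8 rose, 1 fell and 15 did not pass (median 0.26, adjusted p = 1.4e-05). C1s, a protease that starts the classical pathway, had log2 fold changes of 1.98 ± 0.07, 1.48 ± 0.07 and 0.49 ± 0.06 in PMLGH against Model, GelMA against Model and PMLGH against GelMA (edgeR adjusted p = 4.2e-11, 2.6e-09 and 2.5e-04). In the same order its partner C1r had 1.25, 0.86 and 0.39 and C2, the next protease of that pathway, 0.97, 0.56 and 0.41. C7, a part of the membrane attack complex, had 0.41, 0.78 and -0.37, and was the 1 gene of the list that fell in PMLGH against GelMA (adjusted p = 0.019).

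Of 14 genes of apolipoproteins and cholesterol efflux, 9 rose and 5 did not pass in PMLGH against Model (median 0.36, camera adjusted p = 1.7e-04, and adjusted p = 0.13 with an estimated correlation). In GelMA against Model 6 rose, 2 (Lpl -0.37 and Lcat -0.34) fell and 6 did not pass, and the list did not pass (median 0.14, adjusted p = 0.076). In PMLGH against GelMA 4 (Apoe 0.70, Apoc1 1.72, Abca1 0.90 and Pltp 0.34) rose (median 0.18, adjusted p = 3.3e-07). Apoe, the apolipoprotein of macrophages and liver, rose from 166 ± 9.9 CPM in Model to 767 ± 61 in GelMA and 1248 ± 80.4 in PMLGH (SD, n = 3, log2 fold changes 2.91, 2.21 and 0.70 with edgeR adjusted p = 2.9e-12, 1.1e-10 and 4.7e-05). Abca1, the pump that loads cholesterol onto apolipoproteins, rose by 0.96 ± 0.11 in PMLGH against Model and by 0.90 ± 0.11 against GelMA (adjusted p = 1.9e-05 and 2.2e-04), while GelMA against Model gave 0.06 (0.77). Slpi, an inhibitor of neutrophil proteases, had the smallest p in PMLGH against GelMA, with a rise of 1.24 ± 0.07 (adjusted p = 1.6e-07), and rose by 2.44 and 1.20 in PMLGH and GelMA against Model.

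Several epidermal genes were high in a single library. Krt1 had 16.4 CPM in GelMA 4 against 0.663 and 0.656 in GelMA 2 and 3, Krt10 had 16.0 against 0.940 and 0.848, and Dsp, a protein of cell junctions, 4.97 against 1.05 and 0.356. The epidermis list had medians of -0.48, 0.84 and -1.57 in PMLGH against Model, GelMA against Model and PMLGH against GelMA (camera adjusted p = 0.11, 0.71 and 7.7e-04, the last 0.23 with an estimated correlation). The list of basophil and mast cell proteases had -0.09, 0.07 and -0.30 (0.11, 0.71 and 0.0034, the last 0.23 with an estimated correlation), and camera gave the middle one a lower direction. Prss34, uncertain because of its copies, lay at 17.4, 43.7 and 21.3 CPM in Model 1, 2 and 5 and at 4.86, 5.23 and 6.30 in PMLGH 2, 3 and 4, while Mcpt8, a protease of basophils, had a log2 fold change of -0.09 (adjusted p = 0.53).

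The 5 skeletal muscle genes that did not pass in PMLGH against GelMA are Tnnt1 (-0.69), Tnni1 (-0.62), Myl2 (-0.52), Casq2 (-0.42) and Tnnc1 (-0.24), with edgeR adjusted p = 0.087, 0.30, 0.42, 0.43 and 0.45. All 5 are known from slow fibres and heart. In PMLGH against Model, Tnni1 rose by 2.24 ± 0.33, Myl2 by 1.87 ± 0.33 and Casq2 by 2.07 ± 0.27 (adjusted p = 1.7e-04, 6.4e-04 and 5.6e-05), beside a median of 0.62 for their list. Tnnt1 and Tnnc1 had 0.39 and 0.36 there and did not pass. The slow myosin Myh7 passed in PMLGH against GelMA, where it fell by 1.18 (adjusted p = 0.0037).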
